A study of Homo sapiens with 6 samples.

How the data were processed

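RNA from 6 samples of LoVo cells was hybridised to Illumina bead arrays, 2 samples each of cells carrying a control vector, hairpin shLGR5-1 or hairpin shLGR5-2, per the labels. GenomeStudio, Illumina's array software, is named in the submitters' processing notes, with no version stated there. The deposited table used here holds 1 linear intensity per probe and array for 47323 probes. Its values had already been background-subtracted and quantile-normalized by the authors, as the values themselves show: about 30.5% lie below 0 on each array, and at any given rank the arrays differ by at most 0.7. The median intensity was 10.9 to 11.0 on every array. How the background was estimated is not given in the sources used here. A further 12 columns of values were not used, because their names match no sample's labels.

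The test plan, fixed before the data were examined, assumed raw intensities with detection p-values, to be corrected and normalized with limma's neqc. Such columns could not be assigned to samples, so the authors' normalized intensities were used. Each value was set to at least 0, an offset of 16 was added and log2 was taken. Fold changes are therefore on the log2(intensity + 16) scale, which understates the change of dim genes. In place of the planned detection p-values, the noise was estimated as the root mean square of the values below 0, an SD of 10.0, and a probe was kept if it exceeded a threshold intensity of 16.5 on both arrays of at least 1 group; 21792 probes were kept. These replacements were set after the distribution of the values had been seen and before any test was run.

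Probes were named through the platform annotation supplied with the series, with symbols updated through a RefSeq gene table (assembly GRCh38.p14): 30113 probes had 1 gene, 8 had several and 17202 had none listed. Of the first, 30074 symbols were matched through the Entrez identifier, 18 through an accession and 21 were kept as given. The 16269 kept probes with 1 gene were reduced to 12111 genes by taking the probe with the highest mean over the 6 arrays; 3274 genes had several kept probes. The array's own genome build is not given in the sources used here, so no coordinates are printed, and the RefSeq table was used for names, for the chromosome and for the genomic span of each gene.

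All 6 arrays entered 1 linear model with group as its term (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 3 residual and 2.01 prior degrees of freedom). There were 4 contrasts: the mean of both hairpins against shCTL, each hairpin against shCTL, and shLGR5-2 against shLGR5-1. P-values are two-sided, adjusted by Benjamini and Hochberg's method over genes, and a gene is called changed at an adjusted p below 0.05. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 arrays held the same values. Files or labels gave no slide or scan date to test as a batch.

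A probe not above the threshold on either array of a group has only a bound there. Its fold is given as "at least", from the mean log2 intensity of the brighter group over a mean in which each dim value is set to the threshold, without the offset; in the mean of both hairpins such bounds enter for the dim hairpin only. The adjusted p is that of the fit. List medians use fitted values; with dim genes at their bounds, 7 of the 20 called list medians moved by more than 0.05, furthest for NF-kappaB targets under shLGR5-2, from -1.71 to -1.32.

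A set of 30 gene lists with 728 different genes was fixed before the data were examined, from general knowledge of the field. They cover Wnt/beta-catenin targets, intestinal stem cell markers, the LGR and R-spondin system, cell junctions, actin cytoskeleton, integrins and matrix, mesenchymal genes, the MET and STAT3 pathway, MAPK output, drug transporters and metabolism, p53 targets, mitosis, DNA replication, absorptive enterocyte and secretory markers, interferon response, NF-kappaB and chemokines, cholesterol synthesis, ATF4 and the unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, TGF-beta and BMP targets, YAP targets, the Notch pathway, markers of fibroblasts, leukocytes, endothelium and neural cells, and housekeeping genes. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated from the arrays. LGR5 was left out of every list.

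Genes are named by a rule fixed before the data were examined: LGR5; the 12 largest rises and 12 largest falls over both hairpins among called genes whose 4 knockdown arrays all lie on the same side of both controls (2370 and 1963 genes were eligible); the 6 largest each way for each single hairpin by the same criterion and for the direct contrast of the hairpins; and up to 4 list members with the smallest adjusted p in the contrast described. Symbols starting with LOC and unnamed reading frames were passed over, and 1 gene that the rule selects is not described here.

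The fit was tested on simulated data with the means and moderated spread of the real genes, in which 200 bright genes (mean log2 value above 7) among 12111 were changed, so recovery of dim genes was not tested. For both hairpins against shCTL, 2.99% of 1.5-fold, 68.7% of 2-fold and 97.0% of 4-fold changes were recovered, with 6 false calls of 118. For shLGR5-1 against shCTL, none of the 1.5-fold, 32.8% of the 2-fold and 92.4% of the 4-fold changes were recovered, with 7 false calls of 90. In the real data 7111 genes were called over both hairpins, of which 3520 changed at least 2-fold. With so many genes changed, the same adjusted p threshold is less strict, so the simulated recovery rates do not carry over to the real data. Overlap between the hairpins was set beside 100 simulations of unchanged groups against the same controls.

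Alternatives fixed with the plan were a floor of 1 in place of the offset, no filter on dim probes, the replicate number as a block, each array left out in turn, a 2-fold threshold, all kept probes, only the 2 groups compared, and other set tests. After the data were seen, alternatives were added: a stricter threshold of 23.3 on all 6 arrays, an offset of 50, cyclic loess, bright genes only (mean log2 value above 7), and bright genes with each array's trend against genomic span and chromosome removed. The trends with span and chromosome were found by looking through gene properties once the fold changes were known. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.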

Results

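Genome-wide mRNA levels were measured on Illumina bead arrays in LoVo cells, an established human colorectal adenocarcinoma line, after stable lentiviral delivery of a short hairpin RNA. LGR5, the hairpins' target, encodes a receptor for R-spondins, secreted proteins that enhance Wnt signalling, and marks stem cells of the intestinal crypt. The 6 arrays fell into 3 groups of 2: a control vector (shCTL) and 2 separate hairpins against LGR5 (shLGR5-1 and shLGR5-2). The question was which genes changed when LGR5 was knocked down, and whether the 2 hairpins changed the same genes. Values are the authors' normalized intensities, and fold changes are on the log2(intensity + 16) scale with their standard errors (SE). Between 20641 and 20705 of the 47323 probes per array were brighter than the noise threshold of 16.5, and 12111 genes were tested. The number of arrays, 2 per group, limits the precision.

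LGR5 itself was dim in LoVo cells and lower still with each hairpin. Its single probe read 44.4 and 49.2 on the shCTL arrays, -1.1 and 7 on the shLGR5-1 arrays, and 12.5 and 19.2 on the shLGR5-2 arrays. Under shLGR5-1 LGR5 fell at least 2.84-fold, with neither array above the noise threshold (limma, adjusted p = 0.00167), and its fitted log2 fold change depends on the offset: -1.71 with 16, -0.86 with 50 and -4.14 with a floor of 1. Under shLGR5-2 LGR5 fell 1.98-fold (log2 fold change -0.99 ± 0.22, SE, n = 2 against 2, limma adjusted p = 0.0197), with 1 of the 2 arrays above the threshold. The LGR5 call under shLGR5-2 was lost when any 1 of the 4 arrays compared was left out, with an adjusted p of up to 0.115, and it was also lost with a floor of 1 in place of the offset (0.287) or with no filter on dim probes (0.0553).

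**Figure D1:**
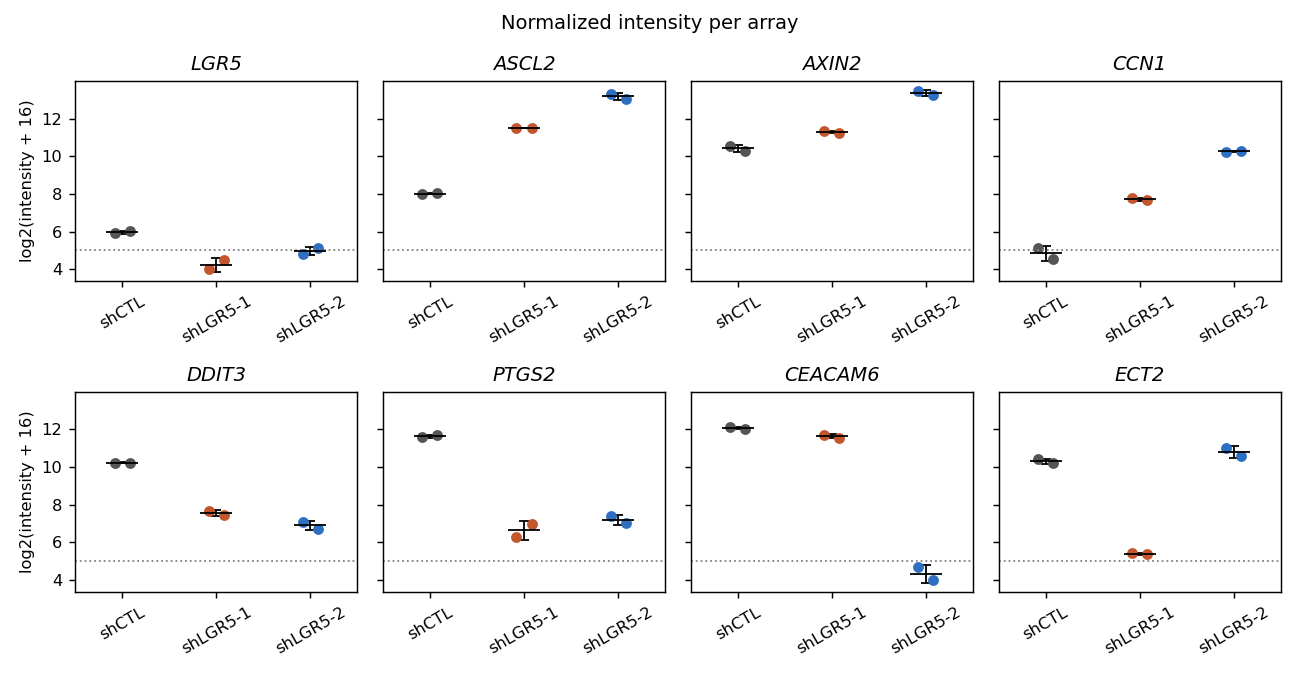
Normalized intensity of 8 genes on each of the 6 arrays, as log2(intensity + 16): filled points are arrays, the bar is the group mean with its SD (n = 2), and the dotted line is the noise threshold of 16.5. LGR5 lies above the line on both shCTL arrays and on 1 of the 4 knockdown arrays, whereas ASCL2 rose and PTGS2 fell under each hairpin and CEACAM6 fell under shLGR5-2.

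Replicate arrays lay close together and the 3 groups far apart. Across the tested genes, replicates correlated at r = 0.991 in shCTL, 0.974 in shLGR5-1 and 0.986 in shLGR5-2. Arrays of different groups correlated at 0.757 to 0.792 for shCTL with shLGR5-1, 0.868 to 0.870 for shCTL with shLGR5-2 and 0.707 to 0.746 for the 2 hairpins with each other. The SD of the log2 difference was 0.315 to 0.562 between replicates and 1.20 to 1.87 between groups.

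The main comparison set the mean of the 2 hairpins against shCTL, and the genes with the largest rise in it were expressed at or near background in control cells. KLK6, a secreted serine protease, was at least 64.4-fold higher (limma adjusted p = 1.40e-04), with a mean intensity of 782 under shLGR5-1 and 1435 under shLGR5-2. GDPD3 was at least 37.5-fold higher, the imprinted non-coding RNA H19 at least 33.2-fold, SERP2 at least 21.6-fold, and NME4, a mitochondrial nucleoside diphosphate kinase, at least 27.6-fold. NDP, which encodes the Frizzled ligand norrin, was at least 23.9-fold higher, and the transcription factor gene TFAP2C at least 16.7-fold. Among genes that control cells did express, the adhesion receptor gene ADGRG1 rose 30.7-fold (log2 fold change 4.94 ± 0.12, SE), ASCL2 rose 19.8-fold (4.31 ± 0.11) and TNNC1 rose 17.4-fold (4.12 ± 0.13). CCN1, above the threshold on 1 of the 2 control arrays, rose 17.7-fold (4.14 ± 0.17).

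The 12 genes named for the largest falls under both hairpins were led by BCAT1 and CALB1. BCAT1, the cytosolic branched-chain aminotransferase, went from a mean intensity of 1463 in shCTL to -2.9 under shLGR5-1 and 15.9 under shLGR5-2, at least 85.9-fold lower over both hairpins, with 1 of the 4 knockdown arrays above the threshold. PTGS2, which encodes the prostaglandin synthase COX-2, went from 3170 to 87.0 and 134, a fall of 26.1-fold (log2 fold change -4.71 ± 0.24, SE). GCNT3, a mucin-type glycosyltransferase gene, fell 23.6-fold on average, and by 2.07-fold under shLGR5-1 against 269-fold under shLGR5-2. Cyclin D2 (CCND2) was at least 36.7-fold lower, the calcium-binding protein gene CALB1 at least 58.5-fold, the ER-phagy receptor gene CCPG1 at least 39.5-fold and kynureninase (KYNU) at least 31.0-fold. For 3 of these the bound holds for the brightest probe, since another probe was above the threshold in the dim group and gave a smaller log2 fold change: CCND2 -3.73, CCPG1 -2.46 and KYNU -3.78. UGT1A6, whose probes could also detect other UGT1A transcripts that share its exons, was at least 29.0-fold lower. Under shLGR5-1 alone CCND2 fell 3.59-fold and UGT1A6 3.75-fold, so most of their average fall came from shLGR5-2. The 2 shLGR5-1 arrays differed for CALB1, at log2 values of 5.09 and 7.23, and its average has an SE of 0.60. MNS1 was at least 28.6-fold, DACH1 at least 28.4-fold, CLRN3 at least 24.7-fold and ANO6, above the threshold on 1 of the 4 knockdown arrays, at least 28.5-fold lower, and the adjusted p of these 12 genes lay between 1.40e-04 and 0.00148.

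In all, 7111 of the 12111 genes changed in this comparison, 3474 higher and 3637 lower, with a median SE of 0.150. Of these, 3520 changed at least 2-fold, 1237 higher and 2283 lower. The SE comes from the spread between arrays of the same group and leaves out the spread between the 2 hairpins. A call for the average can therefore come from 1 hairpin, and 2522 genes were called in the same direction under each hairpin. With the strict filter, which removes genes at background on any array, 3198 genes were higher and 2109 lower. The count was 4607 without shCTL replicate 1 and 4435 without shCTL replicate 2.

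Among the lists of genes fixed beforehand, the stress-response genes regulated by ATF4 and the unfolded protein response fell. Of 26 measured, 22 fell and 1 rose, the same counts when adjusted over the list alone, with a median log2 fold change of -0.97 (camera adjusted p = 7.88e-06; adjusted p = 0.438 with an estimated correlation). Asparagine synthetase (ASNS) fell 5.14-fold, the transcription factor genes DDIT3 and ATF3 fell 8.01-fold and 3.97-fold, and the folate enzyme gene MTHFD2 fell 3.63-fold. Targets of NF-kappaB and chemokine genes were lower as a list: 14 of 23 fell and 4 rose, also over the list alone, with a median of -1.37 (camera adjusted p = 0.0338; adjusted p = 0.438 with an estimated correlation). PTGS2 and the chemokine gene CCL20 (9.39-fold) fell, whereas the chemokine gene CXCL5 and the acute-phase gene SAA1 each rose 10.5-fold, SAA1 from above the threshold on 1 control array. Under shLGR5-1 alone this list was not called (7 higher, 10 lower, median -0.30, camera adjusted p = 0.692).

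Wnt/beta-catenin target genes were higher as a list in the average of the hairpins. Of 21 measured, 14 rose and 4 fell (14 and 5 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 0.0419; adjusted p = 0.438 with an estimated correlation). Besides ASCL2, a transcription factor of intestinal stem cells, the rises included the Wnt feedback inhibitors ZNRF3 (3.86-fold) and AXIN2 (3.71-fold) and the transcription factor gene SP5 (at least 3.60-fold). YAP target genes also shifted upward: 9 of 19 rose and 1 fell, also over the list alone, with a median of 0.71 (camera adjusted p = 0.0482; adjusted p = 0.438 with an estimated correlation). After CCN1 the clearest were CCN2 (5.93-fold), FJX1 (5.24-fold) and NUAK2 (3.81-fold). Under shLGR5-1 alone neither list was called: 12 Wnt targets rose and 2 fell (median 0.67, camera adjusted p = 0.325), and 6 YAP targets rose and 5 fell (median 0.28, 0.781). Both calls for the average are marginal: of 14 alternatives the Wnt list was called in 6 (adjusted p 0.0251 to 0.275) and the YAP list in 5 (0.0117 to 0.392). Both ended with the strict filter, with the replicate number as a block and without shLGR5-1 replicate 2, shLGR5-2 replicate 1 or shLGR5-2 replicate 2, the Wnt call also without shLGR5-1 replicate 1 (0.0531) and the YAP call without shCTL replicate 2 (0.0936) and with a floor of 1 (0.133).

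Genes of mitosis were lower in the average of the hairpins, 22 of 32 falling and 5 rising (22 and 6 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 0.0170; adjusted p = 0.580 with an estimated correlation). The microtubule and kinetochore genes CENPE (4.71-fold, above the threshold on 1 of the 2 shLGR5-1 arrays), NUSAP1 (4.0-fold) and CENPF (at least 6.97-fold) and the cytokinesis regulator ECT2 (4.61-fold) fell. Under shLGR5-2 alone the mitotic list was not called, with 7 higher, 8 lower and a median of -0.04 (camera adjusted p = 0.962). When only bright genes were kept and each array's trend with genomic span and chromosome was removed, an alternative chosen after seeing the data, the list calls for the ATF4 genes (median -1.19, adjusted p = 1.06e-05) and the mitotic genes (median -0.67, adjusted p = 0.0130) were still made. The Wnt, YAP and NF-kappaB lists, with 14, 10 and 16 bright members, were not called among bright genes before the removal (adjusted p = 0.275, 0.275 and 0.0761) or after it (0.141, 0.141 and 0.126). The removal moved their medians from 1.00 to 0.61, from 0.44 to 0.96 and from -1.28 to -1.46.

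Lists closest to LGR5's known biology contained genes that moved in opposite directions. Of 13 measured genes of the LGR and R-spondin system, 7 rose and 4 fell (9 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.253), except with the strict filter (0.0250). The scaffold gene IQGAP1 was at least 11.4-fold lower and the related receptor gene LGR4 at least 4.10-fold lower, whereas ZNRF3 and DVL3 (2.73-fold) rose. Of 15 intestinal stem cell markers, 6 rose and 7 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.827), with ASCL2 and AXIN2 higher, PROM1, which encodes CD133, 14.3-fold lower (above the threshold on 1 of the 2 shLGR5-2 arrays) and ALDH1A1 at least 16.8-fold lower. Of 30 cell junction genes, 11 rose and 13 fell, also over the list alone (camera adjusted p = 0.586): the adhesion genes CDH17 (10.7-fold), CEACAM5 (at least 9.94-fold) and CEACAM1 (at least 3.37-fold) fell and the desmosomal gene PPL rose 5.42-fold. Of 36 actin cytoskeleton genes, 14 rose and 8 fell (15 and 9 adjusted over the list alone; camera adjusted p = 0.390), with LIMA1 12.2-fold lower (above the threshold on 1 of the 2 shLGR5-1 arrays) and CNN2 and ARPC1B each 3.76-fold higher. Of 21 genes of the MET and STAT3 pathway, 6 rose and 8 fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.827), with the receptor genes MET 2.78-fold and IL6ST at least 4.50-fold lower and PIM2 (2.87-fold) and BCL2L1 (2.25-fold) higher.

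**Figure D2:**
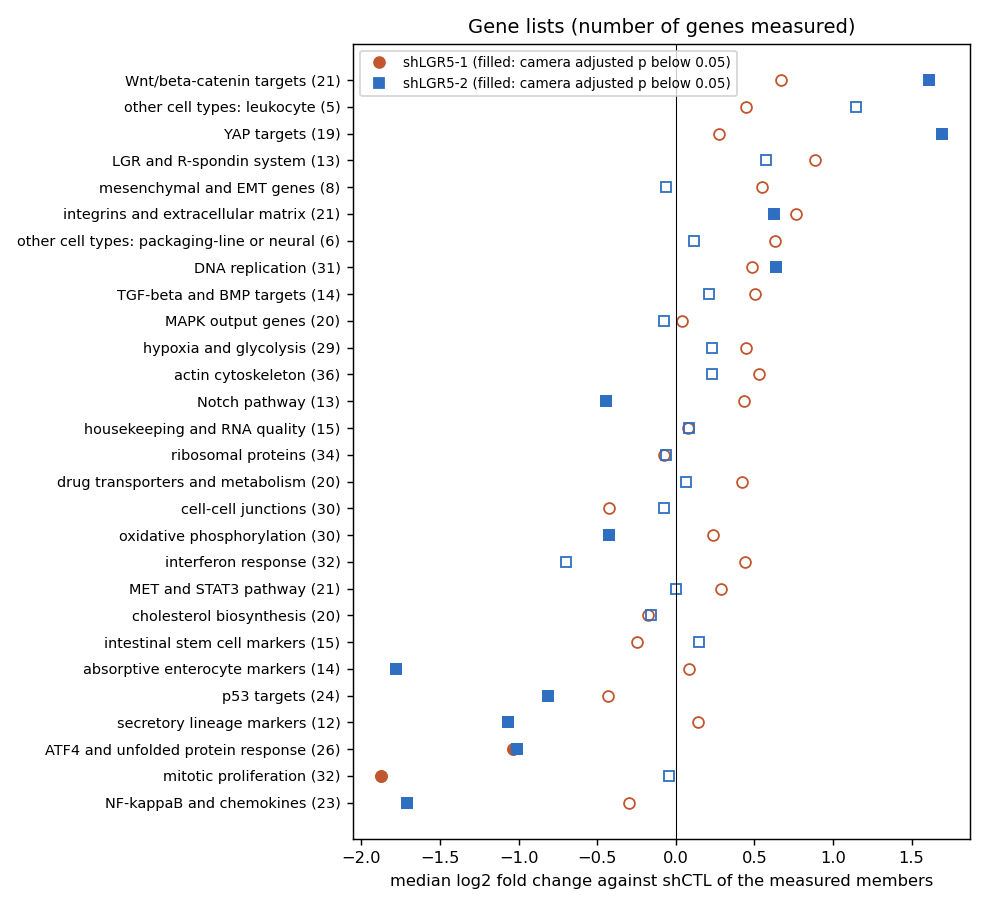
Median log2 fold change against shCTL of the measured members of each gene list under shLGR5-1 (circles) and shLGR5-2 (squares), with the number of genes measured in brackets and filled symbols where the camera adjusted p was below 0.05 with the preset correlation. The ATF4 list lies at -1.04 and -1.01 under the 2 hairpins, the mitotic list at -1.87 and -0.04, and the YAP list at 0.28 and 1.70.

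Under shLGR5-1 alone, genes of mitosis had the lowest median of the lists tested. Of 32 measured, 24 fell and 5 rose, also over the list alone, with a median of -1.87 (camera adjusted p = 7.27e-04; adjusted p = 0.844 with an estimated correlation). ECT2 fell 29.9-fold, CENPF at least 28.9-fold, CENPE 13.7-fold and NUSAP1 12.5-fold. The ATF4 and unfolded protein response list was the other one called, with 17 of 26 falling and none rising, also over the list alone, and a median of -1.04 (camera adjusted p = 7.34e-04; adjusted p = 0.844 with an estimated correlation). ASNS fell 7.26-fold, MTHFD2 6.78-fold, the serine synthesis gene PSAT1 3.96-fold and the endoplasmic reticulum chaperone gene HSP90B1 17.5-fold. Fold changes under shLGR5-1 also followed the genomic span of the gene, with a Spearman correlation of -0.336 across 6999 bright genes, which are not independent replicates. With that trend and the chromosome trend removed, the median of the mitotic genes went from -2.03 to -1.73 (camera adjusted p = 1.33e-04). That of the ATF4 genes went from -0.94 to -1.85 (camera adjusted p = 3.34e-05). The same removal lowered the medians of ribosomal protein genes from -0.08 to -1.03 and of housekeeping genes from 0.08 to -0.48. The lower ATF4 median after it is therefore no sign of a larger fall.

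The largest single changes under shLGR5-1 partly repeated those of both hairpins. KLK6 was at least 47.5-fold, GDPD3 at least 22.2-fold and SERP2 at least 13.5-fold higher, and ADGRG1 and TNNC1 rose 16.1-fold and 14.3-fold. The protease inhibitor gene SPINK6 rose 18.6-fold under shLGR5-1 and was at least 5.15-fold lower under shLGR5-2. BCAT1 was at least 88.9-fold, CCPG1 at least 57.1-fold and MKLN1 at least 59.3-fold lower. TRIM2 fell 50.3-fold, SCAF11 50.8-fold and the virus receptor gene CXADR 47.1-fold, the last with an SE of 0.54, and SCAF11 and CXADR were each above the threshold on 1 of the 2 shLGR5-1 arrays. Another CCPG1 probe gave -2.50, and a dim probe of SCAF11 gave a log2 fold change of -0.25 that did not pass the test. In all, 8701 genes changed, 4885 higher and 3816 lower. Of these, 5992 changed at least 2-fold, 2851 higher and 3141 lower, and with the strict filter 4117 genes were higher and 2099 lower. The median over all 12111 genes was 0.28, so a gene with no measured change ranked below the median gene here. Among bright genes with the trends removed, 5588 of 6996 were called.

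Under shLGR5-2, markers of differentiated intestinal cells were lower as lists. Of 14 absorptive enterocyte markers measured, 9 fell and 2 rose, also over the list alone, with a median of -1.78 (camera adjusted p = 0.00490; adjusted p = 0.211 with an estimated correlation). The lectin gene LGALS4 fell from a mean intensity of 493 to -2.85, below the threshold, the intestinal transcription factor gene CDX1 was at least 27.5-fold lower and keratin 20 (KRT20) at least 10.5-fold, and the mucin gene MUC13 fell 10.5-fold. Of 12 secretory lineage markers, 8 fell and 2 rose, also over the list alone, with a median of -1.07 (camera adjusted p = 0.0172; adjusted p = 0.211 with an estimated correlation). REG4 was at least 145-fold and FCGBP at least 12-fold lower and the Notch ligand gene DLL1 fell 6.16-fold, whereas the goblet-cell peptide gene TFF3 rose 11.1-fold. Genes of the Notch pathway shifted downward, 6 of 13 falling and none rising, also over the list alone, with a median of -0.44 (camera adjusted p = 0.0252; adjusted p = 0.30 with an estimated correlation). HEY2 was at least 13.5-fold lower, and HES6 and HES1 fell 6.09-fold and 1.91-fold. The enterocyte call ended with no filter on dim probes (adjusted p = 0.0573), the strict filter (0.627), bright genes only (0.129) and trend removal (0.101, median -0.83 over 8 genes). The Notch call ended with the last 3 of these (0.107, 0.0845 and 0.116) and without shCTL replicate 2 or shLGR5-2 replicate 2. Over the 8 bright Notch genes the median was -0.57, and -0.59 with the trend removed, so it was not smaller than in the main fit. The secretory call ended without shLGR5-2 replicate 2. The secretory list was tested in only 11 alternatives, against 14 for the other 2 lists. Its 4 bright genes were too few to test among bright genes or with the trend removed.

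The lists of inflammatory, stress and p53 target genes were also shifted downward under shLGR5-2. Of 23 NF-kappaB and chemokine genes, 18 fell and 3 rose, also over the list alone, with a median of -1.71 (camera adjusted p = 4.13e-04; adjusted p = 0.211 with an estimated correlation). The chemokine gene CXCL1 fell 30.1-fold, IL32 26.1-fold and TNF at least 11-fold, whereas CXCL5 rose 37.2-fold. Of 26 ATF4 and unfolded protein response genes, 19 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -1.01 (camera adjusted p = 1.01e-05; adjusted p = 0.211 with an estimated correlation), among them DDIT3 (10.0-fold), ATF3 (7.35-fold), ASNS (3.65-fold) and CHAC1 (3.54-fold). Of 24 p53 targets, 13 fell and 4 rose (13 and 5 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.0293; adjusted p = 0.211 with an estimated correlation). The cell-cycle inhibitor gene CDKN1A fell 5.38-fold and GDF15 4.03-fold, and PHLDA3 was at least 16.4-fold and SPATA18 at least 3.41-fold lower. Of 30 oxidative phosphorylation genes, 15 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 8.17e-04; adjusted p = 0.255 with an estimated correlation). NDUFV1 fell 3.42-fold, UQCRC2 2.53-fold, NDUFA9 2.14-fold and ATP5F1C 1.99-fold. The p53 call ended in 6 of 14 alternatives: a floor of 1 (adjusted p = 0.0575), the strict filter (0.220), bright genes only (0.201), trend removal (0.270), and without shCTL replicate 1 (0.0511) or replicate 2 (0.0503).

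The lists of Wnt targets, YAP targets, DNA replication genes and matrix genes were shifted upward under shLGR5-2. Of 21 Wnt targets, 14 rose and 4 fell (14 and 5 adjusted over the list alone), with a median of 1.61 (camera adjusted p = 0.00592; adjusted p = 0.211 with an estimated correlation). ASCL2 rose 35.4-fold, the receptor gene TNFRSF19 26.6-fold, AXIN2 7.61-fold and LEF1 3.89-fold. Of 19 YAP targets, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 1.70 (camera adjusted p = 0.00101; adjusted p = 0.211 with an estimated correlation), led by CCN1 (42.6-fold), CCN2 (13.2-fold), FJX1 (6.11-fold) and NUAK2 (2.93-fold). Of 31 DNA replication genes, 16 rose and 3 fell (19 and 3 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 9.90e-04; adjusted p = 0.211 with an estimated correlation). RRM2 rose 6.04-fold, TK1 3.82-fold, GINS4 3.36-fold and UHRF1 2.57-fold. Of 21 integrin and matrix genes, 10 rose and 2 fell, also over the list alone, with a median of 0.62 (camera adjusted p = 0.0142; adjusted p = 0.211 with an estimated correlation). The collagen gene COL4A1 was at least 17.2-fold higher, TIMP2 and ITGB5 rose 8.63-fold and 3.13-fold, and the protease gene MMP7 was at least 3.21-fold lower. The Wnt call ended among bright genes (camera adjusted p = 0.0675) and with trend removal (0.0703), and the YAP call with the strict filter (0.119) and among bright genes (0.0526). Over the 14 bright Wnt targets the median was 1.70, and 1.61 with the trend removed. Over the 10 bright YAP targets it was 1.39.

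The largest single changes under shLGR5-2 were losses of genes that were bright in control cells. PI3, which encodes the protease inhibitor elafin, was at least 428-fold lower, CCND2 at least 373-fold, the adhesion gene CEACAM6 at least 261-fold and UGT1A6 at least 222-fold, and GCNT3 fell 269-fold. The other CCND2 probe gave a log2 fold change of -5.59. HBA2 was at least 220-fold lower with its brighter probe, but its second probe gave a log2 fold change of -1.55, and the probes cannot be assigned between the near-identical alpha-globin genes. H19 was at least 110-fold, TMEM52B at least 117-fold, KLK6 at least 87.2-fold and GDPD3 at least 63.4-fold higher, ADGRG1 rose 58.7-fold, and the receptor tyrosine kinase gene KIT rose 74.4-fold from above the threshold on 1 control array. In all, 5349 genes changed, 2617 higher and 2732 lower, 2906 of them at least 2-fold. Genes on chromosomes 5, 7, 12 and 15 were lower as a group, with a median of -0.37 over 1276 bright genes against 0.12 over 5518 on the other autosomes. The count of changed genes was 3084 without shCTL replicate 1 and 3155 without shCTL replicate 2.

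**Figure D3:**
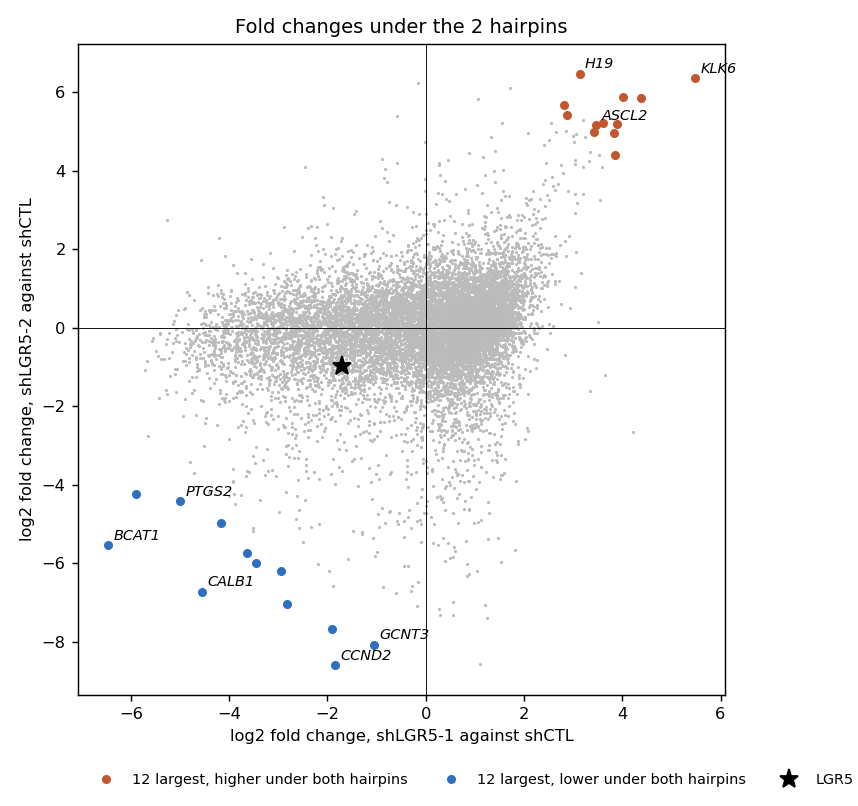
Log2 fold change of each of the 12111 genes under shLGR5-1 (horizontal) and shLGR5-2 (vertical), both against shCTL, with the 12 largest rises and the 12 largest falls of the main comparison in colour and LGR5 as a star. Across all genes the fold changes correlate at r = 0.206. The coloured genes lie in the 2 quadrants where both hairpins moved the same way because the rule that selected them required it.

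More genes were called in the same direction under both hairpins than independent lists would share, by a margin that depended on the processing both for rises and for falls. In both single-hairpin comparisons, 1494 genes were higher and 1028 were lower, 2522 in all, where independent lists of these sizes would share 1056 and 861. With a floor of 1 in place of the offset these were 1384 higher against 795 and 693 lower against 639, and with the strict filter on all arrays 1553 against 1280 and 681 against 556. An offset of 50 gave 1584 higher against 1245 and 1273 lower against 971. No filter on dim probes gave 1341 against 523 and 862 against 428, over 20039 genes. Bright genes only gave 1400 higher against 1109 and 727 lower against 678, over 6996 genes. In the main fit a further 1566 genes changed in opposite directions. The fold changes correlated at r = 0.206 across genes. Simulated unchanged groups set against the same 2 control arrays gave r = 0.50, as the mean of 100 simulations. Equal noise in all groups fixes that value, so the 2 correlations cannot be ranked against each other. The simulations shared 0 called genes, but they held no real change and cannot show what shared controls add among changed genes. The covariance of the fold changes was 0.386 against 0.0339 in the simulation, a difference of 0.352. The 2 controls could not be split into separate sets of 2 arrays, so part of the excess may come from the shared controls, and 1475 and 1481 genes were shared without shCTL replicate 1 and 2 respectively.

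Set directly against each other, the hairpins differed in genes of mitosis and of the Notch pathway. Mitotic genes were higher under shLGR5-2 than under shLGR5-1, 22 of 32 higher and 4 lower, also over the list alone, with a median difference of 1.42 (camera adjusted p = 0.00104; adjusted p = 0.786 with an estimated correlation): ECT2 differed 42.0-fold, CENPF at least 17.2-fold, NUSAP1 9.81-fold and CENPE 8.42-fold. Notch pathway genes were lower under shLGR5-2, 10 of 13 lower and none higher, also over the list alone, with a median difference of -1.88 (camera adjusted p = 0.0375; adjusted p = 0.665 with an estimated correlation), among them HEY2 (at least 25.6-fold), HES6 (7.29-fold), DLL1 (5.76-fold) and LFNG (3.90-fold). Against shCTL, 7 of these 13 rose and none fell under shLGR5-1 (median 0.44, camera adjusted p = 0.368), so part of the difference comes from higher values there. Apart from other set tests, the list calls of this direct contrast were tried under no alternative. The largest single differences were in RHOBTB3 (at least 327-fold), CAPRIN1 (at least 122-fold), RPRD1A (at least 118-fold), CHURC1 (at least 106-fold), KIT (at least 105-fold) and GASK1B (at least 59.3-fold), higher under shLGR5-2. PI3 (at least 926-fold), HBA2 (at least 525-fold), the secreted lectin gene REG4 (at least 337-fold), the mitochondrial creatine kinase gene CKMT1A (at least 293-fold), the glutathione peroxidase gene GPX2 (196-fold, above the threshold on 1 of the 2 shLGR5-2 arrays) and the ribosomal protein gene RPS4Y1 (184-fold) were lower under shLGR5-2. Another probe of RPRD1A gave log2 fold changes against shCTL of -2.38 under shLGR5-1 and 1.76 under shLGR5-2, and 2 dimmer GASK1B probes gave -0.38 and 0.96 under shLGR5-1 and 5.22 and 1.47 under shLGR5-2, so these 2 bounds hold for the brightest probe. The probe of CKMT1A cannot be assigned with certainty between it and its near-identical copy CKMT1B. In all, 8883 genes differed, 4067 higher and 4816 lower under shLGR5-2. This balance depended on the setting. It was 3264 higher and 3076 lower at 2-fold or more, 2324 and 3795 with the strict filter, and 2819 and 2795 among bright genes with the trend removed. The 2 hairpins also differed in how fold changes followed genomic span, with a Spearman correlation of -0.336 under shLGR5-1 and 0.0286 under shLGR5-2 across 6999 bright genes.

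**Figure D4:**
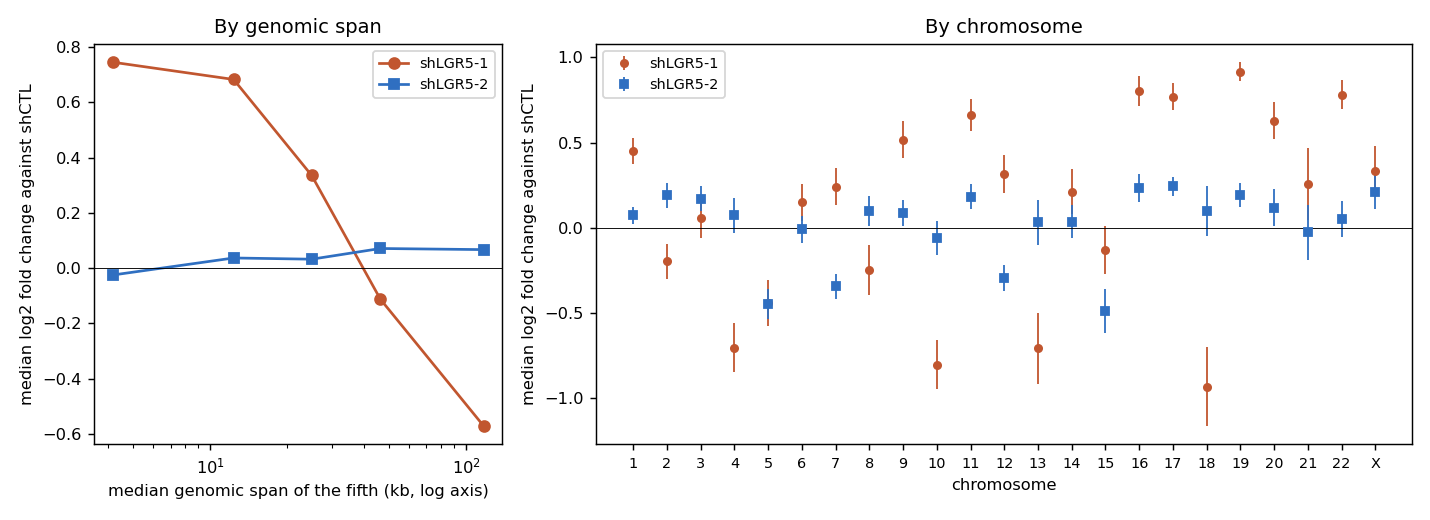
Median log2 fold change against shCTL of bright genes under shLGR5-1 (circles) and shLGR5-2 (squares): left, by the fifth of genes ranked by genomic span, against the median span in kilobases on a log axis; right, by chromosome for the autosomes and X, with the standard error of the median. Under shLGR5-1 the median goes from 0.74 in the shortest to -0.57 in the longest genes, and under shLGR5-2 it is, among autosomes, lowest on chromosomes 15 (-0.49), 5 (-0.45), 7 (-0.34) and 12 (-0.30).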

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

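The tests of genomic span and of paired probes were chosen after the results were seen; the counts after trend removal, the share of calls off chromosomes 5, 7, 12 and 15 and the test on dimmer genes had their predictions written first.

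The 2 hairpins against the same gene differed widely by the test of shLGR5-2 against shLGR5-1, in 8883 genes. The fitted value of LGR5 itself was higher under shLGR5-2 by a log2 difference of 0.72 (± 0.22, SE), a size that depends on the offset. Its probe read -1.1 and 7 on the shLGR5-1 arrays and 12.5 and 19.2 on the shLGR5-2 arrays. Of these only 19.2 lies above the noise threshold, so these arrays cannot settle whether LGR5 differs between the hairpins. Against shCTL, LGR5 under shLGR5-1 and shLGR5-2 was at -0.86 and -0.56 with an offset of 50, and at -4.14 and -1.59 with a floor of 1. Genes of mitosis were higher under shLGR5-2 by a median of 1.42 and genes of the Notch pathway lower by a median of -1.88. Of the 43 genes selected for the size of their change, 42 differed, and PTGS2 was the exception. Those selected for the direct contrast had to pass this same test, and 8883 of all 12111 genes passed it, so the 42 are no separate evidence. All differences here are fitted log2 values for shLGR5-2 minus shLGR5-1, which are not bounds where a group was not above background.

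The genes named for the largest rises under both hairpins were higher still under shLGR5-2: KLK6 by 0.86, GDPD3 by 1.47, ADGRG1 by 1.87, H19 by 3.34, SERP2 by 1.28, NME4 by 1.61, ASCL2 by 1.67, NDP by 2.85, TFAP2C by 1.56, CCN1 by 2.54 and TNNC1 by 0.55. Among genes that fell, BCAT1 (0.93) and CCPG1 (1.66) were higher under shLGR5-2 than under shLGR5-1. CALB1 (-2.16), CCND2 (-6.74), KYNU (-4.22), UGT1A6 (-5.78), MNS1 (-2.54), DACH1 (-2.10), CLRN3 (-3.25), ANO6 (-0.81) and GCNT3 (-7.02) were lower.

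Among genes named for a single hairpin or for the difference, the last chosen for its size, MKLN1 (4.63), SCAF11 (4.82), TRIM2 (2.89), CXADR (5.23), KIT (6.37), TMEM52B (4.40), RHOBTB3 (8.01), CAPRIN1 (6.55), CHURC1 (6.49), RPRD1A (6.28) and GASK1B (5.95) were higher under shLGR5-2. SPINK6 (-6.88), PI3 (-9.66), CEACAM6 (-7.29), HBA2 (-8.63), REG4 (-8.26), CKMT1A (-7.87), GPX2 (-7.61) and RPS4Y1 (-7.52) were lower. Under shLGR5-2 the 4 bright genes of chromosome Y, RPS4Y1 among them, had a median of -2.31 ± 2.37 (SE) against shCTL.

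A first pattern is the wide change under shLGR5-1, in which long genes fell and short genes rose. The Spearman correlation of its fold changes with genomic span was -0.336 (-0.334 and -0.335 on the 2 arrays). Loss of signal from genes with a long span, through poorer RNA or labelling, would go with such a correlation. Genomic span includes introns, however, and neither transcript length nor probe position was tested, so that explanation stays open. The lines may also differ in biology related to span, which was not tested. Noise of single probes is argued against by a correlation of 0.882 between 2 probes of the same gene, over 1437 genes. The mean trend as the whole cause is argued against by 5588 of 6996 bright genes being called after its removal. Of these, 4572 were called in the same direction before. The removal took out 19.3% of the variance and does not touch spread around the mean trend. The SD of the fold changes under shLGR5-1 rose from 0.99 in the group of shortest genes to 1.91 in the longest. Under shLGR5-2 it went from 1.30 to 1.22. Signal loss that varies between genes of similar span would survive the removal, so the count cannot exclude it. How much of what remains comes from such loss, from LGR5, from other targets of this hairpin or from differences between the cell lines stays open.

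A second pattern is the lower level of genes on chromosomes 5, 7, 12 and 15 under shLGR5-2, a set picked from the bright genes. In the 885 dimmer genes on them, not used to pick the set, the median was -0.32 against -0.03 in 4011 on other autosomes, and the 4 again ranked lowest (exact one-sided permutation p = 1.37e-04, the smallest that the 7315 sets allow). Fewer copies of these chromosomes than in the control cells are a candidate explanation, and LoVo is known to carry extra copies of them. Loss of signal from genes with a long span is argued against by a correlation with span of 0.0286. Copy number as the direct cause of all calls is argued against by 2740 of 3433 called bright autosomal genes, 79.8%, lying on other autosomes. These autosomes hold 5518 bright genes against 1276 on the 4, so the calls were spread much as bright genes are. Effects of copy number on genes elsewhere were not tested. Whether a different or selected cell population also lies behind other changes under shLGR5-2 was not tested.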

How the results depend on the processing

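The strict filter on all arrays, the offset of 50, cyclic loess, bright genes only and trend removal were alternatives chosen after seeing the data; the others were planned. No background correction, a median shift in place of quantiles, a slide block and detection p below 0.01 were planned but not run, because they need columns that match no sample or slides that are not given.

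The 60 named gene results kept their direction and call wherever an alternative gave a value. The strict filter gave a value for only 10 of them, and bright genes only and trend removal for 48 each. They were picked as the largest called changes, so keeping a call is weak evidence for them. LGR5 under shLGR5-1 kept its call, at -1.97 to -1.45 when each array was left out. Its size depends on the offset: -4.14 with a floor of 1 and -0.86 with an offset of 50, against -1.71. LGR5 under shLGR5-2 lost its call with a floor of 1 (-1.59), with no filter (-0.99) and when arrays of its comparison were left out (-1.14 to -0.83). LGR5 gave no value among bright genes.

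The correlation between hairpins was 0.269 under the strict filter and 0.192 to 0.229 with an array left out. Requiring a 2-fold change left 3520 genes for both hairpins, 2906 for shLGR5-2 and 1139 shared. With the trend removed, where fewer genes were tested, 5588 changed under shLGR5-1 and 5614 differed between hairpins. Leaving out an array, with a lone array assumed to vary like the other groups, gave 4435 to 7186 genes for both, 7141 to 8609 for shLGR5-1, 3084 to 5523 for shLGR5-2, 7904 to 8787 for the difference and 1475 to 2538 shared. The lowest counts for both, shLGR5-2 and shared genes came without a shCTL array.

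Lists called were, for both hairpins, 7 with no filter on dim probes, 2 among bright genes, 3 with the trend removed, 3 with a replicate block, 0 with an estimated correlation and 25 with fry. For shLGR5-1 they were 3 with the trend removed, 0 with an estimated correlation and 21 with fry. For shLGR5-2 they were 7 with the strict filter, 5 among bright genes, 6 with the trend removed, 0 with an estimated correlation and 21 with fry. Fry asks only whether a list moved, not whether it moved more than other genes. Leaving out an array gave 3 to 5 lists for both, 2 for shLGR5-1 and 9 to 11 for shLGR5-2. Apart from fewer genes or arrays, the cause was not tested. Signal over background limits LGR5, whose brightest array read 49.2 against a threshold of 16.5.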

Other observations

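Trend removal was chosen after the fold changes were seen, as was the test of how much of the Wnt targets' shift it took away; the test of their median after removal had its prediction written first.

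Several lists fixed beforehand were not called over both hairpins although many members changed. Of 31 DNA replication genes 16 rose and 8 fell, also over the list alone (camera adjusted p = 0.197), with GINS4 3.76-fold, TK1 3.59-fold, CCNE1 2.45-fold and MCM5 2.29-fold higher. Of 24 p53 targets 4 rose and 15 fell (5 and 15 over the list alone; camera adjusted p = 0.0825), and the list was called as lower with no filter on dim probes (0.0175) and without shLGR5-2 replicate 1 (0.0444) or replicate 2 (0.0446). Of 21 integrin and matrix genes 10 rose and 7 fell (10 and 8 over the list alone; camera adjusted p = 0.390), with TIMP2 6.82-fold and ITGB4 3.73-fold higher. Of 20 MAPK output genes 8 rose and 7 fell, also over the list alone (camera adjusted p = 0.681), with EGR1 9.15-fold and FOSL1 3.20-fold higher and SPRED1 3.16-fold lower. Of 20 drug transporter and metabolism genes 8 rose and 7 fell, also over the list alone (camera adjusted p = 0.827), with NQO1 5.07-fold higher and MGST1 7.04-fold and ALDH1A3 4.07-fold lower. Of 8 mesenchymal genes 3 rose and none fell, also over the list alone (camera adjusted p = 0.390), among them S100A4 1.78-fold and TGFBI 1.62-fold.

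Of 32 interferon response genes 9 rose and 14 fell (10 and 14 over the list alone; camera adjusted p = 0.681), with OAS3 2.94-fold and IFITM2 4.03-fold higher, MX1 4.80-fold lower and OASL at least 3.20-fold lower. Of 20 cholesterol synthesis genes 2 rose and 8 fell, also over the list alone (camera adjusted p = 0.253), with INSIG1 6.06-fold, CYP51A1 4.42-fold and MSMO1 4.18-fold lower. Of 29 hypoxia and glycolysis genes 13 rose and 5 fell (14 and 5 over the list alone; camera adjusted p = 0.253), with the glucose transporter genes SLC2A3 at least 11.3-fold and SLC2A1 5.30-fold higher and BNIP3 at least 14.3-fold lower. Of 14 TGF-beta and BMP targets 7 rose and 4 fell, also over the list alone (camera adjusted p = 0.681), with SMAD6 at least 6.39-fold lower and BMP4 2.25-fold higher. Of 14 enterocyte markers 3 rose and 8 fell (camera adjusted p = 0.188), of 12 secretory markers 3 and 6 (0.434) and of 13 Notch pathway genes 4 and 4 (0.794), each also over the list alone. Of 30 oxidative phosphorylation genes 2 rose and 9 fell (1 and 8 over the list alone; camera adjusted p = 0.253), and the list was called with the strict filter (0.0454) and, just under the threshold, with no filter.

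Few markers of other cell types were measured. Of 5 leukocyte markers 3 rose and 2 fell, also over the list alone (camera adjusted p = 0.681), with CORO1A 12.1-fold higher, from above the threshold on 1 control array, and CD68 2.54-fold lower. Of 6 neural or packaging-line markers 2 rose and 1 fell, also over the list alone (camera adjusted p = 0.681), with TUBB3 5.34-fold higher and SOX2 at least 3.67-fold lower. Of 4 fibroblast markers FBLN1 was at least 1.90-fold lower in the average, and 2 rose under shLGR5-1 and 2 fell under shLGR5-2. Of 3 endothelial markers none passed in the average, where opposite changes cancel: 2 rose under shLGR5-1 and 2 fell under shLGR5-2. These 2 lists were too short to test as lists. Of 15 housekeeping genes 2 rose and 3 fell (2 and 2 over the list alone; camera adjusted p = 0.969), with ACTB 1.99-fold higher and TFRC 3.44-fold lower.

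Of 34 ribosomal protein genes 2 rose and 8 fell over both hairpins (1 and 5 over the list alone; camera adjusted p = 0.302), with RPL37 5.26-fold, RPL22 3.63-fold and RPS23 3.07-fold lower and RPS7 2.27-fold higher. With each array's trend with span and chromosome removed, their median went from -0.06 to -0.57 and the list was called (adjusted p = 8.27e-04). This came from shLGR5-1 (median -1.03, 27 lower and 1 higher, adjusted p = 2.68e-05), while under shLGR5-2 the median was -0.03 (6 lower, 3 higher, adjusted p = 0.321). Under shLGR5-1 the median before the removal was -0.08, and the list was not called in the main fit (camera adjusted p = 0.692). Trend removal was the only 1 of 14 alternatives with this call, so the call rests on the removal.

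A further pattern is the higher level of Wnt target genes in the average of the hairpins, called over all 21 targets but, among the 14 bright ones, neither in the average (adjusted p = 0.275) nor under shLGR5-1 (0.46 ± 0.35, 0.569) or shLGR5-2 (0.0675). Among the 14 bright targets the median log2 fold change was 1.00 (± 0.52, SE of the median). It was 0.61 (0.605 ± 0.51) once the trend with span and chromosome was removed. That median met the level that the written prediction set against the trend. Less its SE, a margin that the written prediction does not include, it fell short, so at this spread the test is taken as undecided. The shLGR5-2 form of the test (1.61 ± 0.82) was also tried, with the same outcome on each count. Taken gene by gene, a test chosen after both, the removal took away a median of 0.0683 ± 0.13 and 14 of 14 targets kept their sign, which argues against the trend as the whole cause in the average. Under shLGR5-1, which has the span trend, it took away 0.199 ± 0.26 of 0.46 and 10 of 14 kept their sign, which excludes nothing for that hairpin. Under shLGR5-2 the removal took away 0.104 ± 0.083 of 1.70 and 13 of 14 kept their sign. For these bright targets this argues against the trend as the whole cause under shLGR5-2. The trend as a part of this pattern cannot be told apart from no contribution, and whether loss of LGR5 may raise Wnt targets was not tested.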
